A study of Arabidopsis thaliana with 20 samples.

How the data were processed

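The series holds 20 samples of Arabidopsis thaliana. Seedlings were grown for 10 days at 22 °C in cycles of 16 h light and 8 h dark, per the labels. Groups were taken from the sample titles: 4 chromatin-bound RNA libraries for each of the wild type Col-0 and the rz-1b rz-1c mutant, 3 mRNA libraries for each genotype, 5 iCLIP libraries of RZ-1C fused to GFP and 1 of GFP alone. The iCLIP libraries were not analysed here.

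The authors deposited chromatin-bound expression as FPKM in 1 table per genotype, each with 2 replicate columns. The labels give 2 libraries for each replicate number, so they were combined at or before the tables; how is not given in the sources used here. An identical second copy of mutant replicate 2 was the 1 column of per-sample values not used. The authors also deposited a table of both genotypes in mRNA with 1 FPKM-like value per genotype, whose unit is not written in the file, a log2 fold change and a q-value. The log2 ratios here were recomputed from the 2 values, since the deposited log2 column holds text where a value is 0. The submitters' processing notes name the TAIR10 genome, HISAT2 2.0.5, StringTie 1.3.4d, TopHat2 2.1.1, Cufflinks and Cuffdiff 2.2.1, with no role for each. Per the file headers the q-values are adjusted values, and 20851 of 33554 genes have one under 1. All 279 chloroplast and mitochondrial genes are listed at 0 in each table, so these genes are not read, and an exact 0 is reported as listed at 0.

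FPKM divides by a library's total, so a class of RNA that takes a larger share lowers other genes. rRNA made up more of the wild-type columns, and the genotypes stand in separate tables, each column scaled to its own total. The median shift between genotypes is therefore stated, and median-of-ratios and quantile scaling are given beside the main counts. Chromatin-bound RNA includes unspliced and non-polyadenylated transcripts, so a gene's FPKM there is not read against its FPKM in mRNA. Where both are given, what is compared is the change between genotypes or the order of genes within each kind of RNA.

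Relative depth came from the modal ratio of values under 1 FPKM for the same gene in 2 columns. Between 2.34% and 6.15% of such genes lay within the tolerance of the mode, and chained ratios matched the observed mode in 2 of the 3 remaining pairs, with a factor of 2 in the third, as 1 fragment against 2 would give. Total counts per library are not known.

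Differential chromatin-bound RNA was tested with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(FPKM + 1) for genes with a mean of at least 1 FPKM, 2 against 2 columns, with Benjamini-Hochberg adjustment over 19694 genes and a threshold of 0.05. Fold changes on this scale understate the change of low genes. Other folds are ratios of mean FPKM. On simulated data for this comparison with 19612 genes, 4 of 100 genes changed by a log2 of 1 and 70 of 100 changed by 2 were recovered, with 6 false calls. Only these genes were changed there, whereas 3430 were called in the data, so the adjustment was stricter in the simulation. The shares recovered therefore do not give the sensitivity in the data, where smaller changes can still be missed. mRNA calls are the authors' q under 0.05.

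Gene names came from the RefSeq gene table of assembly TAIR10.1, in which 32835 of 33602 identifiers matched. That build differs in name from the authors' build, so coordinates are not printed. The 16 gene lists, of 284 genes, are the RZ-1 family, flowering time, SR splicing factors, other splicing and RNA-binding factors, nuclear photosynthesis, salicylic acid and defence, jasmonate and wounding, abscisic acid with drought and cold, the circadian clock, heat shock, cell division, replication-dependent histones, shoot meristem and leaf shape, seed storage, root markers and housekeeping. They were tested with camera at its preset correlation, with an estimated correlation and with fry, all two-sided and adjusted over the 16 lists. In mRNA a list's median was placed among 10000 random lists matched on expression in 20 bins, as a description of these values. Only members with a ratio and at least 1 FPKM in the higher genotype entered that median. Overlaps and biotypes were tested with two-sided Fisher's exact tests, which treat genes as independent although they are not independent replicates.

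The lists, the tests of each comparison, the rule for named genes and most alternatives were fixed before the data were examined. The agreement after rescaling, the list tests with a replicate left out, with the block or without the filter, the test of biotypes and most tests of explanations were chosen after. Named genes are the RZ-1 family, the 8 largest rises and 8 largest falls among called genes with at least 5 FPKM in the higher genotype and, in chromatin-bound RNA, replicates that do not overlap, up to 4 called members of each list or the 2 highest expressed where none was called, mRNA calls listed at 0 in 1 genotype with at least 5 FPKM in the other, and the 5 genes with the largest summed change in each kind of agreement. Not each of these is printed. Alternatives changed the pseudocount, the filter, the scaling, the threshold, the replicate block and the replicates used. The statistics were computed with Python 3.11.15, SciPy 1.17.1 and pandas 2.3.3, and checked on simulated data, and plots were made with matplotlib 3.10.9.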

Results

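The study measured RNA in 10-day-old Arabidopsis thaliana seedlings of the wild type Col-0 and of the rz-1b rz-1c double mutant. RZ-1B and RZ-1C are glycine-rich RNA-binding proteins of the zinc-finger RZ-1 family with known roles in pre-mRNA splicing. Chromatin-bound RNA, the RNA that stays with purified chromatin and is rich in transcripts still being made, was sequenced from 4 libraries per genotype. These libraries carry 2 replicate numbers, and the deposited table has 1 FPKM column (fragments scaled by gene length and library total) for each number, so n = 2 per genotype. For mRNA the labels give 3 libraries per genotype, and the authors' deposited table holds 1 FPKM value per genotype and a q value for each gene. The labels number these mRNA libraries as 3 replicates. Their names follow the pattern that marks 2 libraries of 1 replicate number in the chromatin-bound set. Whether any of them share a sample is not given. The 5 RZ-1C iCLIP libraries and 1 GFP control library, which map protein contacts on RNA, were not analysed here. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples.

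Low FPKM values move in steps of 1 fragment, and the steps gave the relative depth of the chromatin-bound columns. Set to 1 for wild-type replicate 2, depth was 1.51 for wild-type replicate 1, 2.80 for mutant replicate 1 and 2.98 for mutant replicate 2. Nuclear rRNA genes held 53.6% and 60.5% of the FPKM total in wild-type replicates 1 and 2, against 31.6% and 34.1% in the mutant replicates. The columns listed 11278 and 12290 of 33602 genes at 0 in the wild type and 9446 and 9461 in the mutant. Across the 19694 genes tested, replicates correlated with Pearson's r = 0.953 in the wild type and 0.972 in the mutant, and columns of different genotypes with r between 0.858 and 0.887. These are correlations across genes, which are not independent replicates.

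The first comparison checked the targeted genes in each chromatin-bound column and in the mRNA table. RZ-1C (AT5G04280) was lower in the mutant in both kinds of RNA. Its chromatin-bound FPKM was 16.7 and 13.1 in the wild-type replicates and 4.59 and 4.27 in the mutant replicates, a log2 change of -1.54 (SE 0.21, n = 2 per genotype, limma adjusted p = 0.00523). The authors' deposited table gives its mRNA as 31.7 FPKM in the wild type and 2.77 in the mutant (q = 0.000329). RZ-1B (AT1G60650) was lower in the mutant's mRNA and higher in its chromatin-bound RNA. The authors' deposited table has RZ-1B mRNA at 15.2 FPKM in the wild type and 2.299 in the mutant (q = 0.000329). Chromatin-bound RZ-1B was 10.5 and 9.42 FPKM in the wild type and 132 and 143 in the mutant, 13.8-fold higher (log2 change 3.66, SE 0.17, limma adjusted p = 0.000402). The third family member, RZ-1A (AT3G26420), did not pass, with a log2 change of -0.66 (SE 0.42, limma adjusted p = 0.297), and its mRNA q in the authors' deposited table was 0.565. The RZ-1C call was lost when either mutant replicate was left out (limma adjusted p = 0.0644 and 0.0820, in a range of 0.00125 to 0.0820 over the alternatives), and without wild-type replicate 1 RZ-1A was called lower.

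The second comparison asked how chromatin-bound RNA differs between the genotypes. Among genes that rose were both enzymes specific to the glyoxylate cycle, and among those that fell was a gene of the camalexin pathway. Isocitrate lyase, ICL (AT3G21720), was at 17.2 and 22.7 FPKM in the wild type and 283 and 417 in the mutant, and malate synthase, MLS (AT5G03860), at 3.18 and 2.83 against 66.2 and 54.4. The cycle turns stored seed lipid into sugar, and both genes rose, by 17.5-fold and 20.1-fold (limma adjusted p = 0.000614 and 0.000402). The camalexin pathway gene CYP71A12 (AT2G30750) was at 31.0 and 57.7 FPKM in the wild type, and at 0 and 0.322 in the mutant (limma adjusted p = 0.000614).

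Among the 8 largest rises chosen by the rule for named genes, the seed storage globulin CRA1 (AT5G44120) was listed at 1.14 and 0 FPKM in the wild type and at 44.8 and 58.4 in the mutant. The abscisic acid-responsive gene RD29B (AT5G52300) was listed at 0 in both wild-type replicates and at 22.6 and 21.1 in the mutant. PER1 (AT1G48130), a seed peroxiredoxin, went from 0.453 and 0 to 21.3 and 20.8, and AT3G15670, of the late embryogenesis abundant family, from 0 and 1.18 to 26.9 and 24.4. AT2G47780 was at 0.780 and 0 against 21.8 and 24.6, and AT5G33390 was listed at 0 in the wild type against 16.3 and 21.1. QQS (AT3G30720), a species-specific gene tied to starch metabolism, rose 33.8-fold. FRO2 (AT1G01580), the root ferric reductase, was at 0.148 and 0 in the wild type and at 14.7 and 20.3 in the mutant. On log2(FPKM + 1) these 8 genes had changes between 4.09 and 5.15, which for genes listed at 0 depend on the 1 added.

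Among the falls, AT4G12490 went from 60.0 and 124 FPKM to 0.121 and 0.115, and its relative EARLI1 (AT4G12480) from 41.0 and 90.5 to 1.27 and 2.72. Both encode lipid-transfer-like proteins, and reads could be shared between such neighbouring copies. SAG13 (AT2G29350), a senescence-associated gene, fell from 47.8 and 86.7 to 0.619 and 0.735, and CYP82C2 (AT4G31970) from 26.2 and 45.1 to 0.123 and 0.115. AT1G26390 was listed at 0 in both mutant replicates against 23.5 and 43.2. The pectin methylesterase gene AT2G45220 and AT5G42530 had log2 changes of -4.97 and -4.54. For 7 of the 8 genes made up of these and CYP71A12, with AT5G42530 the exception, wild-type replicate 2 was above replicate 1. In mRNA, the authors' deposited table has SAG13 at 0.0693 against 6.91 FPKM in the mutant (q = 0.227) and CYP82C2 at 0.0112 against 6.98 (q = 0.229). There AT1G26390 was at 0.00957 against 7.70 (q = 0.229), AT5G42530 at 41.8 against 171 (q = 0.000329) and AT2G45220 at 20.2 against 17.2 (q = 0.291).

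limma on log2(FPKM + 1) called 3430 of 19694 genes at an adjusted p under 0.05, 2595 higher and 835 lower in the mutant. The median gene was 0.27 higher in the mutant on the log2 scale. After median-of-ratios rescaling, which sets that median to 0.02, the calls were 1329 higher and 1544 lower, and after quantile normalization 1445 higher and 1541 lower. With mutant replicate 1 or 2 left out the counts were 348 and 227. Without wild-type replicate 1 there were 4988, 4108 of them higher, and 2514 genes were called without wild-type replicate 2, the shallowest column and the one with the most rRNA.

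**Figure D1:**
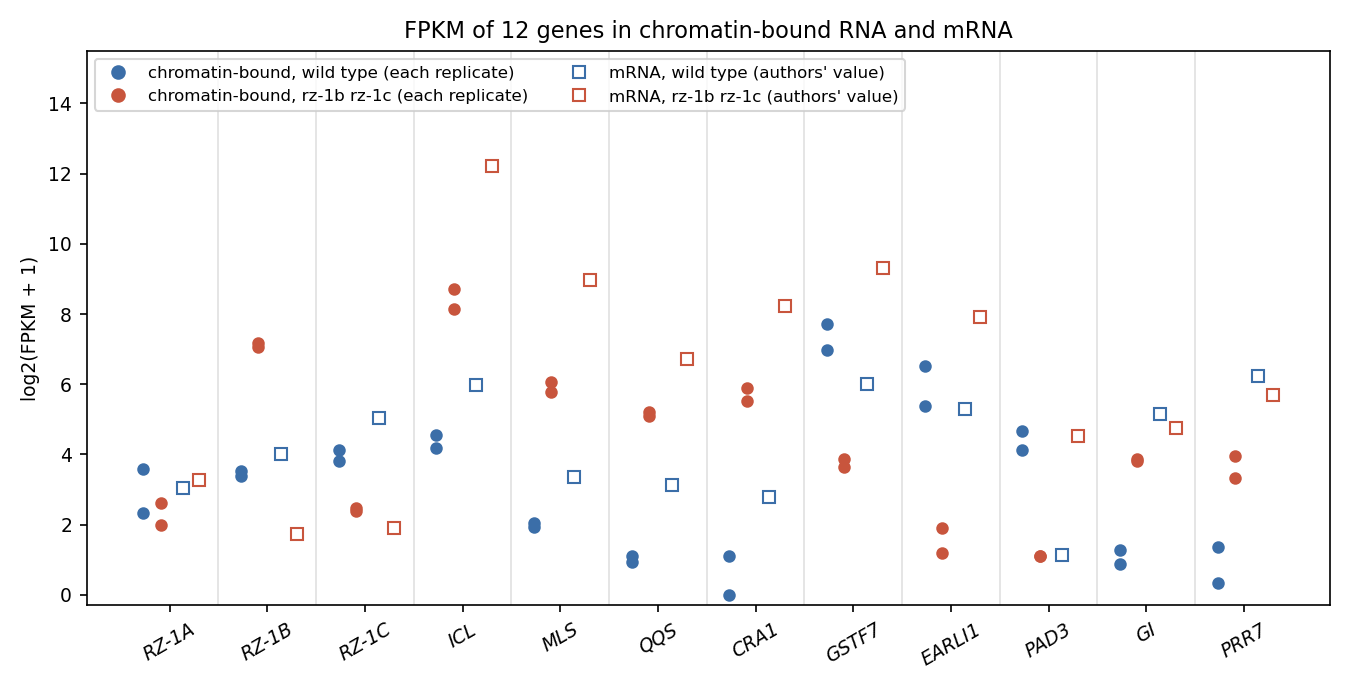
FPKM of 12 genes on a log2(FPKM + 1) axis. Filled circles are the 2 chromatin-bound replicates per genotype and open squares the authors' single mRNA value per genotype, with blue for the wild type and red for rz-1b rz-1c. RZ-1B is higher in the mutant than in the wild type in chromatin-bound RNA, at 132 and 143, and lower in mRNA, at 2.299. ICL is higher in the mutant in both kinds of RNA.

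The gene lists were tested in the chromatin-bound data, and medians are given relative to the 0.27 shift of all genes. With an estimated correlation camera could hardly pass any list at 2 columns per genotype, so those values decide little. Of 9 seed storage genes 4 passed the filter on low values, each only through its mutant values, and these 4 rose (median 2.96 above all genes, camera adjusted p = 0.00177, and adjusted p = 0.648 with an estimated correlation). With all 9 tested, without the filter, camera gave an adjusted p = 0.0192, and adjusted p = 0.694 with an estimated correlation; the other 5 had means under 1 FPKM. The 4 include the cruciferin CRC (AT4G28520), from 0.893 and 0 to 9.58 and 13.2 FPKM, the oil-body protein gene OLEO2 (AT5G40420), from 1.13 and 0 to 10.3 and 17.3, and OLEO1 (AT4G25140), from 0.786 and 0.298 to 2.61 and 3.93. The seed storage list was set as a marker of other tissue. Whether the seedlings of the genotypes matched in tissue make-up or stage was not tested. In the abscisic acid, drought and cold list 9 of 23 rose and 14 did not pass, with 5 rising without wild-type replicate 2 and 6 after rescaling. LEA4-5 (AT5G06760) rose 16.8-fold and ABI5 (AT2G36270), a transcription factor of abscisic acid signalling in seeds, 8.61-fold. The camera test of the list did not pass (adjusted p = 0.160), except without mutant replicate 2, at the preset correlation only.

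Of 21 salicylic acid and defence genes, 10 fell, 1 rose and 10 did not pass (median -1.17 relative to all genes, camera adjusted p = 5.35e-08, and adjusted p = 0.648 with an estimated correlation). PR1 (AT2G14610), the standard marker of salicylic acid signalling, was at 7.63 and 25.2 FPKM in the wild type and listed at 0 in both mutant replicates. The receptor kinase gene FRK1 (AT2G19190) went from 13.2 and 27.0 to 0.843 and 0.386, the camalexin enzyme gene PAD3 (AT3G26830) from 16.6 and 24.3 to 1.18 and 1.14, and PR5 (AT1G75040) from 8.47 and 6.99 to 0.317 and 0.278. Without wild-type replicate 2, 9 members fell. In the jasmonate and wounding list 2 of 20 rose and 1 fell. The fall was LOX2 (AT3G45140), with 125 and 83.1 FPKM against 30.7 and 21.6, and the rises were the lipoxygenase genes LOX3 (AT1G17420), 2.77-fold, and LOX4 (AT1G72520), 1.93-fold. The LOX4 call was lost after rescaling and without wild-type replicate 2, both rises lost their calls with either mutant replicate left out, and the LOX2 fall did without mutant replicate 2.

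Of 21 clock genes, 9 rose and 12 did not pass (median 0.53 above all genes, camera adjusted p = 0.0203, and adjusted p = 0.648 with an estimated correlation). After rescaling 5 were higher and 2 lower. The 4 largest rises were in GI, PRR7, LNK1 and PRR3. GI (AT1G22770) was at 0.826 and 1.42 FPKM in the wild type and 13.6 and 13.0 in the mutant, PRR7 (AT5G02810) at 0.272 and 1.58 against 14.4 and 9.10, LNK1 (AT5G64170) at 0.824 and 1.29 against 15.8 and 11.4, and PRR3 (AT5G60100) at 0.639 and 0.872 against 6.93 and 5.72. The camera call of this list was lost without wild-type replicate 1 (adjusted p = 0.137, in a range of 0.00600 to 0.137 over the alternatives).

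Of 20 SR splicing factor genes, 10 rose and 10 did not pass (median 0.40 above all genes, camera adjusted p = 0.00405, and adjusted p = 0.648 with an estimated correlation). SR45a (AT1G07350) rose 2.45-fold, SR34 (AT1G02840) 2.00-fold, RS41 (AT5G52040) 1.93-fold and SR34a (AT3G49430) 1.87-fold, and 6 of the 20 were called after rescaling, as were 6 without wild-type replicate 2. Among other splicing and RNA-binding factors 4 of 31 rose, namely STA1 (AT4G03430), 2.45-fold, U1-70K (AT3G50670), 2.31-fold, U2AF65A (AT4G36690), 1.84-fold, and SF1 (AT5G51300), 1.81-fold. The last 2 lost their calls after rescaling. Of 17 flowering-time genes 4 rose and 1 fell. FCA (AT4G16280), FPA (AT2G43410) and FLK (AT3G04610), RNA-binding proteins of the autonomous pathway, rose 2.33-fold, 2.14-fold and 2.05-fold, and the flowering repressor SVP (AT2G22540) fell from 11.98 and 12.10 FPKM to 4.62 and 5.19.

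Of 13 replication-dependent histone genes 2 fell and 11 did not pass (median -0.76 relative to all genes, camera adjusted p = 1.74e-05, and adjusted p = 0.648 with an estimated correlation), and after rescaling 7 were lower. The 2 were histone H4 genes, AT5G59690, at 34.9 and 36.0 FPKM against 19.1 and 16.4, and AT2G28740, and H4 copies are so alike that their reads cannot be assigned with certainty. Of 41 nuclear photosynthesis genes 3 rose, 3 fell and 35 did not pass (median -0.44 relative to all genes, camera adjusted p = 0.00183, and adjusted p = 0.648 with an estimated correlation). The antenna genes LHCB2.1 (AT2G05100) and LHCB3 (AT5G54270) rose 2.05-fold and 1.89-fold, and LHCB4.3 (AT2G40100) and the photosystem I gene PSAD2 (AT1G03130) fell by 1.13 and 0.89 on the log2 scale. After rescaling, 0 of the 41 were higher and 12 lower. The root markers held 1 rise and 1 fall among 5, with the iron transporter gene IRT1 (AT4G19690) at 0.243 and 0 against 9.83 and 14.7 FPKM and PRP3 (AT3G62680) at 5.77 and 5.74 against 2.68 and 2.57. The PRP3 call was lost without wild-type replicate 2 and with either mutant replicate left out.

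KNAT1 (AT4G08150), a meristem homeobox gene, rose 2.49-fold and was the 1 call among 6 shoot meristem and leaf shape genes. limma called 0 of 9 heat shock, 0 of 9 cell division and 0 of 9 housekeeping genes, of which 2, 1 and 0 had an unadjusted p under 0.05. Among the heat shock genes HSP70-4 (AT3G12580) had a log2 change of 0.43 and HSP101 (AT1G74310) of -0.10, among the cell division genes KNOLLE (AT1G08560) had -0.70 and CYCB1;2 (AT5G06150) -0.33, and among the housekeeping genes EF1A (AT5G60390) had 0.32 and GAPC2 (AT1G13440) -0.07. The camera test did not pass for shoot meristem and cell division (adjusted p = 0.0942 for each), jasmonate (0.0761), housekeeping (0.160), flowering time (0.396), other splicing factors (0.443) or root markers (0.781). The jasmonate list was called lower without wild-type replicate 2 (adjusted p = 0.00429), without mutant replicate 1 (0.000228) and without the filter on low values (0.0373), and cell division without wild-type replicate 2 (0.0283), by camera at its preset correlation. By camera with the replicate number as a block, the jasmonate list was also called lower (adjusted p = 0.0131). The root markers were called higher among genes with a mean of at least 5 FPKM (camera adjusted p = 0.0488), where 1 member remained. With an estimated correlation none of these lists was called in these settings. With mutant replicate 1 or 2 left out, 0 and 0 SR factors, 2 and 2 clock genes, 4 and 3 abscisic acid genes and 3 and 1 seed storage genes were called higher, and 5 and 4 defence genes lower. In both of these fits 0 flowering-time genes, 0 other splicing factors, 0 photosynthesis genes, 0 histone genes and 0 shoot meristem genes were called. Adjusted over the list alone, the counts of higher and lower genes were 14 and 0 for SR factors, 2 and 11 for defence, 12 and 2 for the clock, 10 and 0 for abscisic acid, 3 and 6 for photosynthesis, 4 and 1 for flowering, 2 and 1 for jasmonate and 0 and 2 for histones, and the other lists kept their numbers. The RZ-1 family had a median of -0.93 relative to all genes and did not pass by camera (adjusted p = 0.443, with a negative sign), but was called higher by fry (adjusted p = 0.0277), which looks at a list's members without setting them against other genes. The heat shock list, with a median 0.02 above all genes, passed neither by camera (adjusted p = 0.443, with a negative sign) nor by fry (adjusted p = 0.768, with a positive sign). Of the 6 lists called by camera, fry passed the clock (adjusted p = 0.0192) but not seed storage, defence or SR factors (0.0614 for each), histones (0.145) or photosynthesis (0.768), and it also passed shoot meristem (0.00413) and flowering time (0.0277), both higher. The calls by fry moved with rescaling: the clock (adjusted p = 0.0528), flowering time (0.154) and the RZ-1 family (0.0823) were lost, shoot meristem passed (0.0418), and so did SR factors (0.0174), histones (0.0403), photosynthesis (0.0418) and housekeeping (0.0253), the last 3 lower. The sign for the heat shock list by fry was then negative, without a call (0.802).

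**Figure D2:**
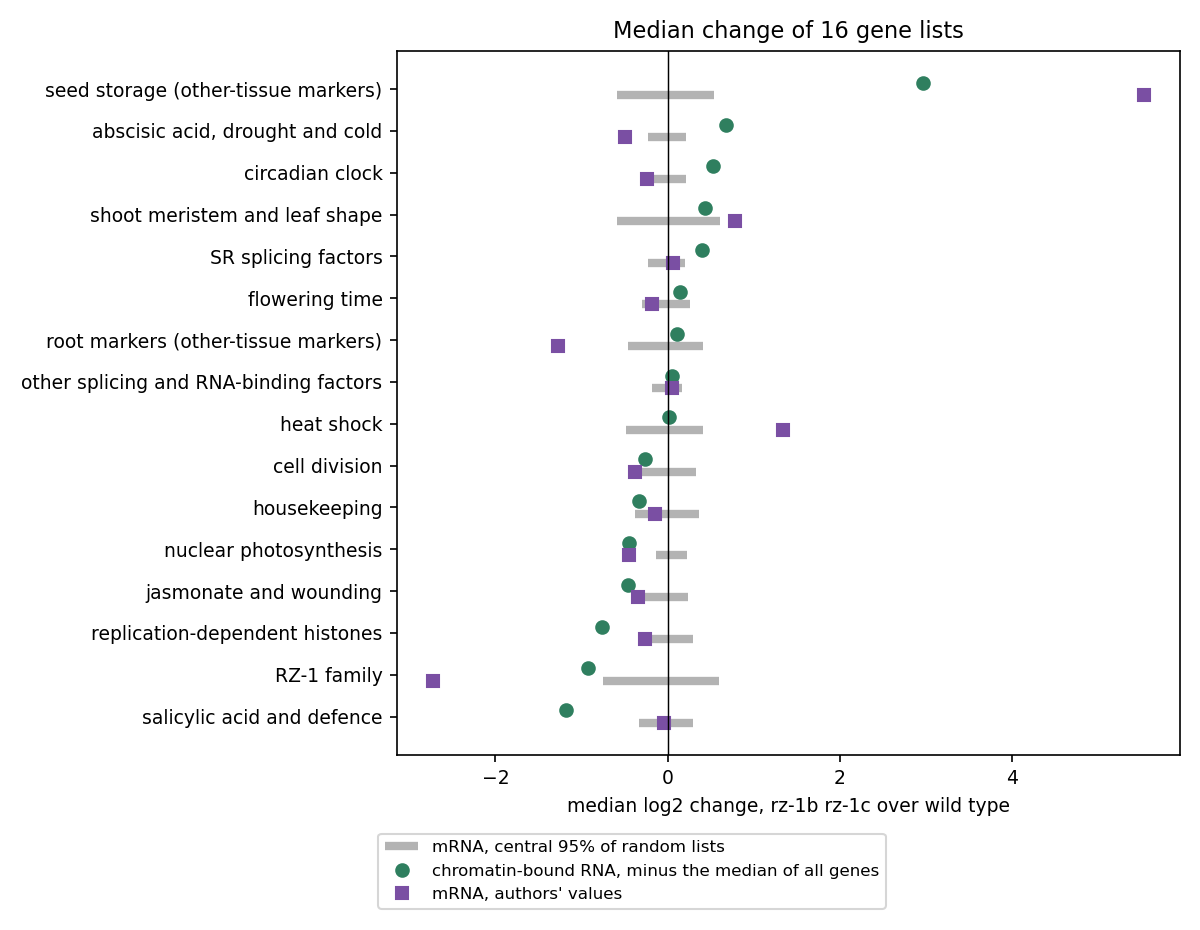
Median log2 change of 16 gene lists, rz-1b rz-1c over the wild type. Circles are chromatin-bound medians minus that of all genes, squares mRNA medians from the authors' values, and grey bars the central 95% of random lists matched on expression. The seed storage list, with 4 of its 9 genes tested in chromatin-bound RNA and 7 in the mRNA median, is highest in both kinds of RNA. The defence list is at -1.17 in chromatin-bound RNA and at -0.04 in mRNA.

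The third comparison took the same genotypes in mRNA. ICL, MLS and CRA1 were higher in the mutant here too. In the authors' deposited table ICL mRNA was 61.9 FPKM in the wild type and 4773 in the mutant, MLS 9.23 against 505, and CRA1 5.92 against 300 (q = 0.000329 for each). Among the largest ratios, the authors' deposited table has AT2G42560 at 0.0947 FPKM in the wild type and 38.9 in the mutant, AT5G44310 at 0.220 and 83.6, EM1 (AT3G51810), a seed maturation protein gene, at 0.209 and 56.2, and AT3G15670 at 2.37 and 406. The other 4 of the 8 largest, AT4G36600, AT4G21020, ECP63 (AT2G36640) and AT5G66780, had log2 ratios between 7.18 and 7.52 in the authors' deposited table.

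Among called genes above 0 in both genotypes and at 5 FPKM or more in the wild type, PAP14 (AT2G46880) had the largest fall. The authors' deposited table lists it at 11.9 FPKM in the wild type and 0.0923 in the mutant. Called genes listed at 0 in 1 genotype have no ratio and were not ranked among the rises or falls. AT3G05727 fell from 446 to 5.15 in the authors' deposited table, AT4G14060 from 18.5 to 0.244, AT3G62950 from 25.9 to 0.499 and AT1G64590 from 32.2 to 0.845. A group of neighbouring genes fell together in the authors' deposited table, with AT4G22485 at 151 against 3.51, AT4G22505 at 128 against 2.66 and AT4G22517 at 124 against 2.80. These 3 also fell in chromatin-bound RNA, by 2.15, 2.39 and 2.65 on the log2 scale (limma adjusted p = 0.00158, 0.00188 and 0.000752).

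The authors' deposited table holds 7221 of 33554 genes with q under 0.05, 3532 higher and 3689 lower in the mutant. Of these, 41 are listed at 0 in the wild type and 17 at 0 in the mutant in the authors' deposited table. Its smallest q, 0.000329, is shared by 3168 genes of the authors' deposited table, so q does not rank them, and without values per library neither a spread nor a left-out replicate can be given.

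By list, the authors' deposited table has 5 of 9 seed storage genes higher and 0 lower, 6 of 16 heat shock genes higher and 1 lower, and 5 of 11 shoot meristem genes higher and 0 lower. Their medians were 5.54, 1.34 and 0.78. They rest on the 7, 13 and 8 members with a ratio and at least 1 FPKM in the higher genotype. Members such as CRC, at 0.731 against 69.1 FPKM in the authors' deposited table, pass only through the mutant. The medians lay at percentiles 100, 100 and 99.1 of 10000 expression-matched random lists from the authors' deposited table. OLEO2 was at 2.59 and 177 FPKM in the authors' deposited table, HSP17.6A (AT5G12030), a small heat shock protein gene, at 0.536 and 4.97, and the boundary gene CUC1 (AT3G15170) at 0.459 and 2.46.

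Photosynthesis genes were lower in 21 of 41 and higher in 4 in the authors' deposited table (median -0.45, percentile 0). The antenna gene LHCB1.4 (AT2G34430) was at 8092 FPKM in the wild type and 4351 in the mutant in the authors' deposited table, while the Rubisco small subunit genes RBCS1B (AT5G38430) and RBCS2B (AT5G38420), near-identical copies whose reads may be shared, rose 2.03-fold and 2.01-fold. All 6 root markers were lower in the authors' deposited table (median -1.27, percentile 0.03), among them PRP3 at 81.1 against 27.7 FPKM and IRT1 at 8.71 against 2.47. Of the cell division list 4 of 9 were lower in the authors' deposited table (median -0.38, percentile 2.06), including CYCB1;2 at 24.5 and 13.5. The RZ-1 family, with 2 of 3 lower, was at percentile 0 in the authors' deposited table.

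Hormone and clock lists moved in both directions. In the authors' deposited table the abscisic acid, drought and cold list had 13 of 25 lower and 7 higher (median -0.50, percentile 0.01), with RD29B at 3.93 against 130 FPKM and the cold regulator CBF1 (AT4G25490) at 13.6 against 0.361. In the jasmonate list 8 of 22 were lower and 3 higher (median -0.34, percentile 0.84), and the authors' deposited table has VSP1 (AT5G24780) at 29.5 against 1.41 FPKM, LOX4 at 17.0 against 2.58 and LOX2 at 47.0 against 98.8. Clock genes were lower in 7 of 21 and higher in 3 in the authors' deposited table (median -0.24), with ELF4 (AT2G40080) at 38.2 against 18.4 and PRR3 at 3.04 against 9.15. Defence genes were higher in 7 of 24 and lower in 5 in the authors' deposited table (median -0.04, percentile 44.7), with PAD3 at 1.18 against 22.0 FPKM, CYP71A13 (AT2G30770) at 0.323 against 27.9, and WRKY40 (AT1G80840) at 80.4 against 6.59.

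Flowering-time genes were lower in 6 of 24 and higher in 1, with FPA at 11.6 against 36.4 FPKM in the authors' deposited table, SVP at 59.3 against 20.5, and FT (AT1G65480), the mobile flowering signal, at 0.979 and listed at 0 in the mutant. SR factors were higher in 2 of 20, RS31a (AT2G46610) and RSZ22a (AT2G24590), and other RNA-binding factors higher in 3 and lower in 2 of 31, with GRP7 (AT2G21660) at 1803 against 1261 FPKM in the authors' deposited table. Histones were lower in 3 of 13, and of 9 housekeeping genes ACT2 (AT3G18780) and ACT8 (AT1G49240) were lower and EF1A higher in the authors' deposited table.

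The fourth comparison set the chromatin-bound changes beside the mRNA changes. AT3G15670, CRA1, ICL, MLS and AT3G02480 had the largest summed changes among genes that changed the same way in both. AT3G02480 was at 2.38 and 3.61 FPKM in wild-type chromatin-bound RNA and 52.1 and 58.2 in the mutant, and at 53.3 against 2893 in the authors' deposited table. GSTF7, CYP71A12, EARLI1, AT4G12490 and AT1G26380 had the largest summed changes in opposite directions. The glutathione transferase gene GSTF7 (AT1G02920) had chromatin-bound FPKM of 126 and 211 in the wild type and 13.6 and 11.4 in the mutant, and mRNA of 63.4 against 631 in the authors' deposited table. CYP71A12, lower in chromatin-bound RNA, was at 0.870 against 116 in the authors' deposited table, EARLI1 at 38.4 against 239, AT4G12490 at 1.47 against 24.2, and AT1G26380 at 0.328 against 33.4.

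Across 18551 genes the 2 sets of log2 changes had Spearman's rho = 0.26 and Pearson's r = 0.28, as values across genes, which are not independent replicates. Of 6253 genes called in the authors' deposited table, 63.9% had the same sign in chromatin-bound RNA. Among 18771 genes tested in both, 936 were higher in both against 404.6 for independent lists (Fisher's exact test, adjusted p = 1.63e-174), and 242 lower in both against 126.8 (adjusted p = 1.87e-25, Fisher's exact test). In opposite directions, 226 were lower in chromatin-bound RNA and higher in mRNA against 137.3 (Fisher's exact test, adjusted p = 1.34e-15), and 156 the reverse against 373.6 (Fisher's exact test, adjusted p = 2.17e-46). After rescaling of the chromatin-bound columns 583 were higher in both against 199.9, 463 lower in both against 238.4, 307 lower in chromatin-bound RNA and higher in mRNA against 258.3, and 53 the reverse against 184.5. The kinds of RNA came from separate libraries, and no test of the difference between them could be made without mRNA values per library. In wild-type chromatin-bound RNA the dawn gene LHY (87.1 and 93.1 FPKM) was above GI (0.826 and 1.42). In wild-type mRNA it was below GI, at 3.07 against 34.5, and the dawn genes CCA1, RVE2 and RVE8 showed the same order. The labels give no hour of harvest, so a different hour for the 2 kinds may have shaped this comparison and was not tested.

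**Figure D3:**
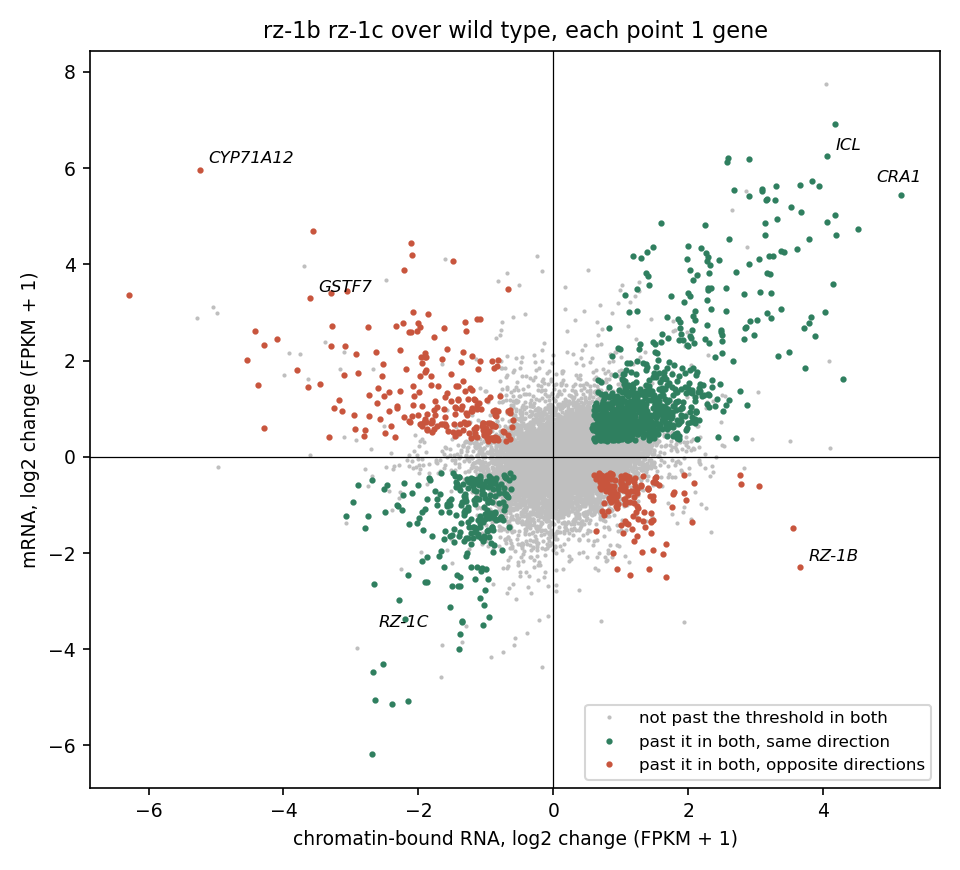
Log2 change in chromatin-bound RNA (x axis) and mRNA (y axis), rz-1b rz-1c over the wild type on log2(FPKM + 1), each point 1 gene. Of the 1560 genes past the threshold in both, 1178 changed in the same direction (green) and 382 in opposite directions (red), with RZ-1B at 3.66 in chromatin-bound RNA. Genes without an mRNA ratio, or under 1 FPKM in the mRNA of both genotypes, are in these counts but are not drawn.

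The planned comparison of changes by intron number was not made, since the gene table used here gives no exon counts.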

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

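The test of the genes beside RZ-1B was fixed before its result was seen; the other tests in this part were chosen after. The genes named next, written here with their chromatin-bound log2 changes, passed in both kinds of RNA with opposite signs, and the difference between the kinds of RNA was not tested. They are CYP71A12 (-5.24), AT4G12490 (-6.29), AT1G26380 (-3.56), EARLI1 (-4.42) and GSTF7 (-3.60), lower in chromatin-bound RNA and higher in mRNA, and RZ-1B (3.66), which went the other way.

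RZ-1B was 13.8-fold higher in mutant chromatin-bound RNA although its mRNA was lower. A difference in scale is argued against by the log2 change of 3.39 that remained after median-of-ratios rescaling, and reads shared with RZ-1A or RZ-1C by their summed level, at most 9.37 FPKM where RZ-1B was at least 132. If transcription of the disrupted locus ran into its neighbours, an adjacent gene would rise, and AT1G60640 did, with a log2 change of 1.04 (limma adjusted p = 0.0358), whereas CB5LP on the other side had 0.20 (adjusted p = 0.687). The rise of AT1G60640 is modest, since 1549 genes rose by at least 1, so run-on transcription from the altered locus is a candidate explanation that stays open. An effect of the missing proteins on RZ-1B itself was not tested.

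The defence list was lower in mutant chromatin-bound RNA, with 10 of 21 members down. Scale is argued against by a list median of -1.17 after rescaling. Whether values near the floor were the whole cause is not decided. The list kept its camera call among genes with a mean of at least 5 FPKM (15 members, adjusted p = 0.00174, and adjusted p = 0.629 with an estimated correlation). Members that fell, such as PR1, FRK1 and PAD3, pass that filter only through their wild-type values. The 19 members at or above 5 FPKM in the wild type, also chosen on wild-type values, had a median of -0.83 relative to all genes. They moved both ways (14 below all genes, two-sided exact sign test, p = 0.0636). A defence state that varied between wild-type harvests may contribute: over the 10 members that fell, wild-type replicate 2 exceeded replicate 1 by a median of 0.70 beyond all genes, in 9 of the 10. That difference rests on 2 columns, so such a state and an effect of the mutations cannot be told apart, and the effect of genotype stays open, untested, with 5 of the 10 higher and 1 lower in mRNA, and 7 higher and 5 lower over the whole list.

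GI, LNK1, PRR7 and PRR3 were 8.37-fold to 12.8-fold higher in mutant chromatin-bound RNA. Scale is argued against by a smallest log2 change of 1.87 among the 4 after rescaling. In mRNA, GI and PRR7 were both lower, with the larger log2 ratio at -0.40, and PRR3 was higher, at 1.59. These values cannot decide whether the chromatin-bound rise held at every time of day. Chromatin-bound RNA and mRNA can differ, since 382 genes, RZ-1B among them, were called in opposite directions. A later hour of harvest for the mutant chromatin-bound seedlings could raise such genes, but the dawn genes CCA1, LHY, RVE8 and RVE2, chosen after their values were seen, had a median of -0.027 relative to all genes, which decides nothing because they moved both ways. The hour of harvest and a changed clock in the mutant cannot be told apart, since the labels give no hour of harvest.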

How the results depend on the processing

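The agreement after rescaling, and the list tests with a replicate left out, with the block or without the filter, were added after seeing the data. Of 764 pairs of a named gene and an alternative in chromatin-bound RNA, 656 kept direction and side of the threshold, 89 lost the call, 11 gained one and 8 changed sign. Of the 89, 57 came from leaving out a mutant replicate; a lone column is then assumed to vary like the wild-type pair, whose spread is wider. Of 166 such pairs in mRNA 155 were the same and 11 missed q under 0.01, and of 144 pairs for lists 136 were the same.

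Chromatin-bound calls numbered 1931 (1418 higher, 513 lower) with no filter, where more low genes enter the adjustment, and 2139 (1549 higher) with a log2 change of at least 1 required. Rescaling gave 1329 higher and 1544 lower, quantile normalization 1445 and 1541; both move the median gene to near 0. Leaving out each replicate gave 227 to 4988 calls, 113 to 4108 higher and 114 to 880 lower, and RZ-1C log2 changes from -1.70 to -1.38. In mRNA a log2 change of at least 1 left 2975 genes (1386 higher, 1589 lower), and on log2(FPKM + 1) 2043 (950 and 1093).

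With an estimated correlation 0 lists were higher and 0 lower, against 3 and 3. At 2 columns per genotype that version has few residual degrees of freedom and could hardly pass any list. The clock list lost its call although its estimated correlation was -0.036, so its loss is not evidence of correlated genes. For the other lists called at the preset correlation the estimates were positive. They were 0.96 for seed storage, 0.38 for SR factors, 0.37 for photosynthesis, 0.26 for histones and 0.20 for defence. Genes in those lists may move together, so their camera adjusted p at the preset correlation may be too small. Leaving out each replicate gave 2 to 4 lists higher and 3 to 5 lower. Spearman's rho between the kinds of RNA was 0.21 at 5 FPKM or more in both, 0.25 with no filter, 0.37 over mRNA calls alone and 0.22 to 0.28 with each replicate left out. The share with the same sign was 62.5% with no filter, 66.1% after rescaling, and 61.1% to 66.6% with each replicate left out; the cause was not tested.

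Signs changed for HSP101 (-0.45 to 0.25 with each replicate left out: 0.25 without wild-type replicate 2, 0.14 without mutant replicate 2), GAPC2 (-0.15 to 0.022: 0.011 without wild-type replicate 1, 0.022 without mutant replicate 2) and RVE8 (-0.091 after quantile normalization, -0.20 after rescaling, -0.098 without wild-type replicate 2, -0.027 without mutant replicate 1), which pass no threshold in these fits; the cause was not tested.

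With the replicate number as a block, limma called 4520 genes and camera the jasmonate list (adjusted p = 0.0131, and adjusted p = 0.560 with an estimated correlation). Differences between replicates 1 and 2 correlated at 0.01 across all genes between the genotypes, which gives no pairing over all genes, although jasmonate genes shifted alike in both. No paired analysis was possible for mRNA because the table has 1 value per genotype. Separate libraries within a replicate number, per-library mRNA fits and changes by intron number were not run, and removing organellar genes changes nothing because they are listed at 0.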

Other observations

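Tests in this part were chosen after the values were seen. Genes of snoRNAs, tRNAs, miRNAs and lncRNAs, pseudogenes and transcribed pseudogenes were more often higher in mutant chromatin-bound RNA than other genes were, while for snRNA genes, with 2 of 11 higher and 0 after rescaling, no difference passed (Fisher's exact test, adjusted p = 0.647). Of 67 snoRNA genes tested 46 rose and 0 fell, 68.7% against 13.0% of other genes (Fisher's exact test over 8 biotypes, adjusted p = 6.86e-25), and after rescaling 33 were called. For tRNA genes 29 of 76 rose (adjusted p = 6.2e-08, Fisher's exact test), for miRNA genes 27 of 69 (adjusted p = 8.15e-08), for lncRNA genes 39 of 154 (adjusted p = 6.58e-05), for pseudogenes 79 of 193 (adjusted p = 1.59e-21) and for transcribed pseudogenes 52 of 162 (adjusted p = 8.91e-10). After rescaling 24 tRNA, 15 miRNA and 24 lncRNA genes, 57 pseudogenes and 33 transcribed pseudogenes were called higher. Each of these classes still passed (Fisher's exact test, largest adjusted p = 0.000154). These tests treat genes as independent, but genes of a class can shift together with a column. Their p-values therefore do not measure the spread between replicates. The snoRNA, tRNA and miRNA genes also differed between wild-type replicates, with medians of replicate 2 minus replicate 1 of -0.77, -0.50 and -0.36 on the log2 scale, against -0.033, 0.11 and -0.20 in the mutant. The share of rRNA was 53.6% and 60.5% in wild-type replicates 1 and 2, and 31.6% and 34.1% in the mutant. Whether that difference shaped these rises was not tested. For snoRNA genes, there were 39 rises without wild-type replicate 2. The transcribed pseudogene AT2G35743 was at 2102 and 2170 FPKM in the wild type and 9748 and 10010 in the mutant.

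The iron-uptake genes FRO2 and IRT1 rose in chromatin-bound RNA, with log2 changes of 4.09 and 3.55, whereas in the authors' deposited table FRO2 was at 1.57 against 1.93 FPKM (q = 0.423) and IRT1 at 8.71 against 2.47. Jasmonate genes differed between replicate numbers in both genotypes, with list medians for replicate 2 minus replicate 1 of -0.86 in the wild type and -0.88 in the mutant, against -0.17 and -0.08 for all genes.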
